A study of Caenorhabditis elegans with 31 samples.

How the data were processed

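The series measured where messenger RNAs of Caenorhabditis elegans end, by polyA capture in 17 libraries and by cloned RACE products in 8 sets. For polyA capture, per the labels' protocols, the authors made cDNA from polyA RNA with a biotinylated oligo-dT primer, cut it with DpnII, kept the 3′ pieces on beads, added barcoded linkers and amplified them in 2 rounds of PCR. The deposited capture tables, 1 for the pilot and 1 for the full experiment, hold counts: whole numbers of reads of each distinct tag sequence in each library, with linkers and tail already removed. How the authors called, trimmed or corrected the tags is not stated. For RACE, per the labels, the authors amplified transcripts of mixed-stage worms with transcript-specific primers, cloned the products, pooled 1 colony per clone pool into each of 8 sets, and sequenced the sets. Those deposited files hold read sequences with linkers removed and the authors' BLAT alignments of them to a genome whose build is not stated. The Illumina sequencing of clone sets was not analysed here.

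Tags name genes only through a genome or transcripts, and neither sequence was at hand. The chromosome sizes in the authors' alignments also differ from those of the WBcel235 annotation, so no coordinate of one was used with the other. Every test planned per gene was therefore run per tag locus, and loci are reported by sequence and counts. The tests of fixed gene lists could not be run, because the lists name genes. A locus label such as tag-00001 gives the rank of the locus by total reads.

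A locus gathered the tags that begin at the same DpnII site. Tags shared a locus when the first 14 bases after GATC were the same once runs of 1 base were shortened to that base, since run lengths varied between reads of otherwise identical tags. A key 1 edit from another key with at least 5 times the reads was merged into it. Loci cut at different starts were linked when they shared at least 3 shortened words of 18 bases and at least 50% of the words of the smaller. All joined tags also had to match in sequence, with edits at no more than 10% of up to 120 bases, and linked loci had to share at least 20 bases. Every copy of GATC at the start of a tag, whole or with 1 base lost, was removed before the key and the end positions were set. This was done because the barcode of the L2 and daf-9 libraries is also GATC. True sequence that starts with such bases after the first GATC was removed too. In the sequences printed here a repeated GATC was removed once. These rules gave 74598 loci before linking and 65492 after it, of which 8418 held at least 10 reads. Loci of near-identical gene copies may be merged, so a locus can stand for more than 1 gene.

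The locus rules were set after the tags had been seen. Word length, merging and linking were settled before any stage was compared. The agreement of sequences was required only after the stage comparisons had been run once, because the loci then picked out for site use joined unlike sequences. Results without that requirement are among the alternatives, chosen after seeing the data like those for the key length, the merge ratio, linking, small sites, the doubtful library and the extreme stages. The tests of families and chromosomes, with their alternatives, were also chosen after seeing the tags. All other alternatives, the planned comparisons and the rule for named loci were fixed before the data were examined.

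Counts per locus were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors and filterByExpr, which left 3121 loci. All 17 libraries entered 1 fit with a coefficient per group and an additive term for the experiment, pilot or full. Adjusted p-values are Benjamini-Hochberg values over the loci tested, with a threshold of 0.05. The SE given with a fitted log2 change was derived from the test, as the absolute change over the square root of its F statistic. Library totals ran from 45142 to 510423 reads, and 85.9% to 97.0% of a library's reads fell in loci. The common biological coefficient of variation was 0.854. The term for the experiment is a block on replicate number: replicate 1 of the 6 shared stages is the pilot and replicate 2 the full experiment, per the labels. Libraries of the same experiment also deviated together from their stage means, with correlations of 0.160 to 0.527 over the 15 pairs of stages. Whether replicates came from separate cultures is not stated, so p-values measure the spread between these libraries. Intervals and floors cover counting error only, because PCR copies are not separate molecules.

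A fold change against a group with 0 reads is a lower bound, computed against 3 counts over the whole group and written as at least so many fold. Dauers and males were in the full experiment alone, so their ratios and bounds are taken against the full-experiment library of L3 or of hermaphrodites, a choice made after the first results were seen. Where a group held 1 to 3 reads, the ratio is given with its 95% counting interval. Named loci follow the planned rule without its gene symbols. In each contrast these are up to 2 loci that rose and 2 that fell, with the largest fitted changes among those past the threshold whose libraries did not overlap between the groups. The planned part of the rule on gene lists gave no names. For site use, the rule asked for the most used sites to lie at least 20 nt apart and to differ by at least 20 percentage points between stages.

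Some loci could be placed in protein families, because their longer tags reach into the coding sequence. A family was called when at least 3 distinct tags that also held the locus's own 3′ sequence encoded a peptide of the family. The peptide patterns were chosen after the tags had been seen and before the stages were compared, and several were tried: shorter ribosomal patterns were dropped because they matched too widely, and ubiquitin and chaperone patterns were dropped too. This gave 20 loci of ribosomal proteins, 8 of collagens, 7 of major sperm proteins and 1 of actin. The call can rest on few reads: tag-00001, with 134489 reads, is called ribosomal from 29 of them. Likewise tag-00078, with 3527 reads, is called collagen from 5, and tag-00317, with 879, major sperm protein from 12. Families, and sets of loci by chromosome, were tested with limma's camera (limma 3.58.1) on log2 CPM values with a preset correlation of 0.01, and again with an estimated correlation. Adjustment was over the families, or over the chromosomes, of a contrast. Replacing TMM by DESeq2's size factors (DESeq2 1.42.0) shifted the median change of all loci by at most 0.133 on the log2 scale and turned the direction of no family that passed its test.

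A 3′ end is the last base of a tag, and ends within 10 nt of a more used end of the locus form 1 site. Sites of at least 10 reads were kept, 9830 in 7966 loci. An end whose sequence did not match that of the most used end was left out, which removed 840 of 87437 end positions and 2041 of 2124177 reads. The mean end position of a library was the mean deviation from the locus mean over loci with at least 2 sites and at least 10 reads in each of the 12 libraries of the shared stages. Its correlation with stage order was tested by permuting stages within experiments, 100000 times or exactly, two-sided. Site use was tested with edgeR's diffSpliceDGE. That function tests 1 coefficient at a time, so each later stage was tested against embryo, the 5 p-values of a locus were combined by Simes' method, and the result was adjusted over loci. AATAAA was searched in the 40 nt before each end in the tag itself, and shares were compared by Fisher's exact test, two-sided, with 95% Wilson intervals. A RACE read was placed on a locus by an exact anchor of 20 bases, and its end was compared with the capture sites of that locus. The background is the same share with ends shifted by 200 nt. Because few tags are that long, a shift of 25 nt was added.

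A locus was given a chromosome when at least 3 RACE reads placed on it had a single alignment and at least 90% of them lay within 100 nt of each other. This placed 943 loci.

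The tests of counts, of end position and of site use were first run on simulated data. For counts these were drawn from the real means, library sizes and spread. For end position, invented loci had equal reads in every library and only counting error. For site use, the real totals of loci were used with a preset spread that was not estimated from the data, so its shares of calls may not carry over. The other tests (camera, Fisher's and sign-flip tests, the permutation test of tag length and the RACE shares) were not run on simulated data. For L4 against L3, with 2351 loci in the fit and 50 loci changed at each size, the edgeR test called 2% of loci changed 4-fold, 6% at 8-fold, 12% at 16-fold and 28% at 32-fold. Of its 25 calls, 1 was false, and in the simulated comparison of L2 with L1, where nothing changed, it made 0 calls. The slope of end position was found as 1.49 nt per stage where 1.5 was simulated, on 100 loci. For site use across the 6 stages, on 1281 loci, the test called 29.5% of the 166 loci whose shares changed by more than 50 points, and 0% of its calls were false.

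Alternatives were other scaling, filters, locus rules and site rules, DESeq2 or limma in place of edgeR, no experiment term, and each library left out in turn. Other analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.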

Results

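The 3′ ends of messenger RNAs were profiled through worm development. PolyA capture, which reads the stretch between the last GATC of a cDNA and its polyA site, was run on 17 whole-worm libraries. A pilot of 6 libraries covered embryos, the 4 larval stages L1 to L4 and adult hermaphrodites, with 1 library each. The full experiment of 11 libraries repeated those 6 stages once and added 1 library of adult males and 4 of dauer larvae, the arrested alternative to the third larval stage, each from another daf mutant (daf-2, daf-7, daf-9 and daf-11). Fed worms were taken about 8 h after plating for L1, 20 h for L2, 30 h for L3, 45 h for L4 and 70 h for adults. RACE, which amplifies the 3′ ends of chosen transcripts, was sequenced in 8 sets of clones from mixed-stage worms.

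The capture tables held 2437080 reads of 636042 distinct tags. Pilot libraries held 45142 to 73224 reads. In the full experiment the 6 shared stages held 74456 to 510423 reads, the male library 201557 and the dauer libraries 50331 to 76289. Log levels of the same stage correlated between the experiments at r = 0.497 to 0.795 across loci, which are not independent replicates, and those of the dauer libraries at 0.703 to 0.820. Only 3 of the 12 stage libraries had their highest correlation with the other library of their stage. The adult hermaphrodite library of the full experiment stood apart: 45.2% of its reads came from 1 locus, tag-00003, and 40000 reads drawn from it held 1063 loci, against 2697 to 6082 in the other 16 libraries.

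Levels were compared along development to find which transcripts differ between stages. Across the 6 stages, 890 of 3121 tag loci changed in edgeR's quasi-likelihood F test. By mean share of reads, ribosomal protein loci were lowest in embryos, major sperm protein loci were first seen after the embryo at L4, and collagen loci were highest in adults. Of the family tests between stages given below, only the rise of major sperm protein at L4 also passed with an estimated correlation (camera adjusted p = 0.0115). Major sperm protein, the cytoskeletal protein of nematode sperm, took 0.220% ± 0.0789 (SD, n = 2) of the reads in loci at L4 and 0.152% ± 0.109 (SD, n = 2) in adult hermaphrodites, with 0 reads in the L1, L2 and L3 libraries. Collagen, the main material of the cuticle, took 1.43% ± 0.361 (SD, n = 2) in adult hermaphrodites, 0.143% ± 0.132 at L4 (SD, n = 2) and 0 reads in embryos. Most of the adult collagen reads, 1154 in the pilot and 818 in the full library, came from 1 locus, tag-00078, with 1284 in both. That locus is called collagen from 5 of its 3527 reads. Of the reads in ribosomal protein loci, 86.8% over all libraries came from tag-00001, which is called ribosomal from 29 of its 134489 reads, and the share of the other ribosomal loci was also lowest in embryos, 0.739% in the pilot and 0.0652% in the full experiment. The count of 890 became 453 without the pilot embryo library, 279 without the full embryo library and 1550 without the pilot adult hermaphrodite library.

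**Figure D1:**
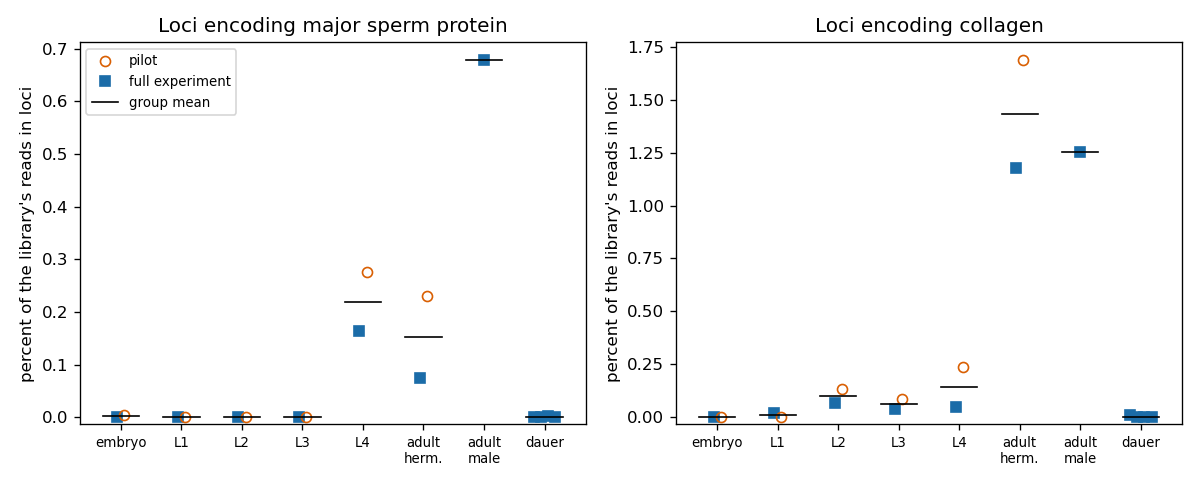
Percent of each library's reads in loci that fell in loci encoding major sperm protein (left) and collagen (right), by stage, with open circles for the pilot, filled squares for the full experiment and lines for group means. Major sperm protein loci reached 0.220% at L4 and 0.678% in the 1 male library, with 0 reads at L1 to L3. The collagen share was highest in adult hermaphrodites, with a mean of 1.43%, mostly from 1 locus, tag-00078. That locus is called collagen from 5 of its 3527 reads.

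From embryo to L1, 290 loci rose and 46 fell. Ribosomal protein loci rose as a group: the median log2 change of the 15 tested was 3.83, and 9 of them passed the test on their own. The group's camera adjusted p was 8.11e-06, but adjusted p = 0.209 with an estimated correlation. Among these, tag-00100 rose by 4.68 ± 1.15 on the log2 scale (SE, edgeR adjusted p = 0.00188), from 55 to 426 reads, and tag-00119 by 4.66 ± 1.11 (SE, edgeR adjusted p = 0.00143), from 92 to 441 reads. Of single loci, tag-00213 (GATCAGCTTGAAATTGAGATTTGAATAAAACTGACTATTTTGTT) had 378 reads in L1 and 0 in embryos, at least 346-fold higher. Likewise tag-00268 (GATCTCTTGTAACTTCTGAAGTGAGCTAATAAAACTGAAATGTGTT) had 358 reads in L1 and 0 in embryos, at least 316-fold higher. In the other direction, tag-00072 on chromosome V (GATCAAATAAATTCATTTCGCTGTC) had 3751 reads in embryos and 0 in L1, at least 252-fold lower, and tag-00162 (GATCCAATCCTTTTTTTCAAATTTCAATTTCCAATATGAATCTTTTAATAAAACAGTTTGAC) had 1610 and 0, at least 174-fold lower. The count of 336 loci became 54 without the pilot embryo library, 18 without the full embryo library, 182 without the pilot L1 library and 77 without the full L1 library, and 628 when the full adult hermaphrodite library was kept out of the shared spread. DESeq2 called 352 that rose and 31 that fell, but tag-00072 and tag-00162 were not among them (DESeq2 adjusted p = 0.233 and 0.288). Without the full embryo library tag-00072, tag-00213 and tag-00268 did not pass (edgeR adjusted p = 0.0711, 0.0815 and 0.123).

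Between L1 and L2 a single locus passed the test. This was tag-00033 on chromosome IV (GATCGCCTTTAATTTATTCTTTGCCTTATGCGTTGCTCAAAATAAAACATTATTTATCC), which rose by 7.67 ± 1.25 on the log2 scale (SE, edgeR adjusted p = 2.71e-06), from 13 reads in L1 to 2931 in L2. The 7 collagen loci tested had a median log2 change of 0.65 and a camera adjusted p = 0.0269, with adjusted p = 0.315 with an estimated correlation. The 15 ribosomal protein loci tested had a median of 1.05 and the same camera adjusted p = 0.0269, with adjusted p = 0.466 with an estimated correlation. The share of reads in all ribosomal loci nonetheless fell, from 7.73% to 7.27% in the pilot and from 12.5% to 8.51% in the full experiment. Apart from tag-00001 it rose, from 3.86% to 4.11% and from 0.546% to 1.04%. Without the pilot L1 library 0 loci passed edgeR's test, DESeq2 called 15 with all libraries, and 40 passed when the full adult hermaphrodite library was kept out of the shared spread. At an unadjusted p under 0.05 there were 144 of 3121 loci, no more than that threshold gives where nothing changes.

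Between L2 and L3, 0 loci passed edgeR's test. At an unadjusted p under 0.05 there were 150 loci, DESeq2 called 1, and 2 passed when the full adult hermaphrodite library was kept out of the shared spread. The 150 loci, of 3121 tested, are no more than an unadjusted p under 0.05 gives where nothing changes. Changes between these stages were not detectable at this spread between libraries, which does not show that they are absent.

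At L4, major sperm protein loci came up. The family held 561 reads at L4 and 0 of 235346 at L3, which allows a share of up to 0.00127% there, so its share was at least 147-fold higher at L4. Of its 7 loci 5 were tested, and of these tag-00317 had 279 reads at L4 and 0 at L3 (edgeR adjusted p = 0.00137), at least 117-fold higher, and tag-00378 had 213 and 0 (edgeR adjusted p = 0.00569), at least 72.0-fold higher. The family call of tag-00317 rests on 12 of its 879 reads and that of tag-00378 on 498 of its 747. The group's camera adjusted p was 5.47e-11 and held with an estimated correlation, with adjusted p = 0.0115. In all, 15 loci rose from L3 to L4 and 0 fell in edgeR's test. The largest rises were those of tag-00102 (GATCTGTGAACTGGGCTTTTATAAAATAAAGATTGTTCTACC), with 794 reads at L4 and 0 at L3, at least 214-fold higher, and tag-00392 on chromosome II (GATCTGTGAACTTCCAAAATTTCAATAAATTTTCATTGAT), with 592 and 0, at least 156-fold higher. Among the 7 collagen loci tested 1 rose, tag-00078, with 41 reads at L4 and 0 at L3 (edgeR adjusted p = 0.0291), at least 12.3-fold higher. The collagen group had a camera adjusted p = 0.0327, and adjusted p = 0.166 with an estimated correlation. Of all loci, 233 had an unadjusted p under 0.05, and DESeq2 called 1, not tag-00392. The 15 became 1 without the pilot L3 library, 1 that fell without the full L3 library, 2 without the full L4 library, and 53 when the full adult hermaphrodite library was kept out of the shared spread.

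From L4 to adult hermaphrodite, 7 loci rose and 4 fell, and 2 of the risen loci are called collagen. The collagen locus tag-00682 (its tag begins GATCCCCAGGAAACGATGGAGAGTCTGGAA) had 293 reads in adults and 0 at L4, at least 132-fold higher, and tag-00078 rose from 41 to 1284 reads (edgeR adjusted p = 0.00516). The other 5 collagen loci tested did not pass, and of these tag-01137 went from 101 to 8 reads and tag-02253 from 52 to 5. Another risen locus, tag-00304 on chromosome IV (its tag begins GATCCCGTCGTTAAAAACGAGTTTTCTTTT), had 265 reads and 0, at least 103-fold higher. Of the fallen, tag-00196 (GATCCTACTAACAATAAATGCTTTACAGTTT) had 0 reads in adults and 261 at L4, at least 57.2-fold lower, and tag-00423 (GATCCGAATTAAATAAAAGTTGAAGTTTTC) had 0 and 153, at least 32.7-fold lower. As groups, the camera adjusted p was 0.0145 for collagen, upward, and 0.00107 both for major sperm protein and for ribosomal proteins, downward. With an estimated correlation each of these had an adjusted p = 0.135. Apart from tag-00001, which went up from L4 to adult in the pilot and down in the full experiment, the ribosomal loci took a smaller share in adults in both: 2.97% against 4.71% in the pilot and 0.155% against 0.545% in the full experiment. Of the 11 loci, 10 also passed without the adult library of the full experiment, which held 1372 loci, and in that fit 24 rose and 4 fell. With DESeq2 tag-00682 did not pass (adjusted p = 0.340). Without the pilot adult library 59 rose and 530 fell, with DESeq2 12 rose and 77 fell, and 0 passed without 1 or the other of the L4 libraries, so the balance of rises and falls is not established.

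Dauer larvae were set against L3, the stage they replace, and 106 loci were higher in dauers and 223 lower. The 4 loci with the largest changes were each seen in 1 of the groups alone, and folds are given within the full experiment, which held all dauers. In dauers tag-00168 (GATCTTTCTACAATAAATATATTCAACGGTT) had 1623 reads, against 0 at L3, at least 350-fold higher, and tag-00267 (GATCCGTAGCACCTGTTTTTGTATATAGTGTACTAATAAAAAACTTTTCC) had 1055 reads and 0, at least 214-fold higher. Both loci had reads in all 4 mutants, and each bound is for the mean level of the 4. By contrast tag-00033 on chromosome IV, the locus that rose at L2, had 760 reads in the full L3 library, 258 in the pilot one and 0 in the 4 dauer libraries, at least 448-fold lower, and tag-00145 on chromosome I (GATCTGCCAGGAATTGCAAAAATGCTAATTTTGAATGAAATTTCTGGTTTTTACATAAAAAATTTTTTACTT) had 331, 114 and 0, at least 195-fold lower. Of 7 collagen loci tested 2 were lower, tag-00451 and tag-01137, each with 44 reads at L3 and 0 in dauers (edgeR adjusted p = 0.00170 and 0.0189), at least 23.6-fold lower from 40 reads in the full L3 library and at least 10.6-fold lower from 18. Of 15 ribosomal protein loci tested 1 was lower, tag-00100, with a log2 change of mean levels of -3.14 within the full experiment (edgeR adjusted p = 0.0183). Both groups had a camera adjusted p = 0.0371, downward, and an adjusted p = 0.390 for collagen and 0.519 for ribosomal proteins with an estimated correlation. The mutants stand for dauer alone, so genotype and stage cannot be told apart. Neither tag-00168 nor tag-00267 passed with DESeq2 (adjusted p = 0.1198 and 0.141), which called 128 higher and 204 lower, or without the full L3 library. The count of 329 became 43, all lower in dauers, without that library, and 590 when the full adult hermaphrodite library was kept out of the shared spread.

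Adult males were compared with adult hermaphrodites to find loci that differ between the sexes, with 1 male library, which was assumed to vary like the other groups. Males were higher at 110 loci and lower at 6. The highest above hermaphrodites was tag-00035 (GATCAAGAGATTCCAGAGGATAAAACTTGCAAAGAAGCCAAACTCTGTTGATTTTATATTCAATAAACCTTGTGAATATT), with 7763 reads in males and 0 in hermaphrodites, at least 2224-fold higher within the full experiment, followed by tag-00149 (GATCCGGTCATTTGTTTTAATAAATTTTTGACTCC), with 1782 and 0, at least 511-fold higher. Lower in males was tag-00145 on chromosome I, with 1 read against 30 in the full hermaphrodite library and 256 in the pilot one, a ratio within the full experiment of 34.9 with a counting interval of 5.80 to 1424. Its fitted log2 change was -6.96 ± 2.14 (SE, edgeR adjusted p = 0.0428), and -4.96 or -8.31 with 1 hermaphrodite library left out. Another was tag-00004 (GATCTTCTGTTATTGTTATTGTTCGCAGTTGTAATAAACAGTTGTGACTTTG), with a log2 change of -3.20 ± 1.00 (SE, edgeR adjusted p = 0.0460). Major sperm protein loci took 0.678% of the male reads, with a 95% exact binomial interval of 0.641% to 0.717%. Of the 5 loci tested, tag-01211 was higher, with 150 reads in males and 5 in hermaphrodites (edgeR adjusted p = 0.0243), and the group had a camera adjusted p = 0.00190, with adjusted p = 0.153 with an estimated correlation. Of loci at 100 CPM or more in the pilot hermaphrodite library, 59.47% had no read in the full one, against 0.0103% expected from counting. A 0 in the full library may thus be no counting limit, so the folds of tag-00035 and tag-00149 within the full experiment are not firm lower bounds. Over all loci the median log2 change was 2.06 in favour of males, and the full hermaphrodite library held 1372 loci. Against that, the medians were -1.07 for collagen and -0.46 for ribosomal protein loci, with camera adjusted p = 9.68e-04 and 0.0122, and with adjusted p = 0.0784 and 0.282 with an estimated correlation. None of these loci passed on its own, and the collagen share of the male library, 1.25%, lay between those of the hermaphrodite libraries, 1.18% and 1.69%. None of the 6 lower loci passed with DESeq2 size factors, where tag-00145 and tag-00004 had edgeR adjusted p = 0.0531 and 0.0733, and these 2 did not pass without the term for the experiment either, at 0.0697 and 0.226. DESeq2's own test called both but neither tag-00035 nor tag-00149 (adjusted p = 0.195 and 0.266). The count of 116 became 712 without the pilot hermaphrodite library and 18 without the full one, of which 7 were higher in males and 11 lower. In that last fit, which sets males against the pilot hermaphrodites alone, tag-00035 and tag-00149 kept log2 changes of 15.04 and 13.76, against 15.64 and 13.75 with all libraries, but did not pass.

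The number of ends found per locus rose with its reads. Ends before and after a GATC generally fall in different loci and were then not counted together. Of 7966 loci with a site of at least 10 reads, 1333, or 16.7%, had more than 1 such site, and 992 of these had 2. A locus under 20 reads can show only 1, and the share was 47.0% of the 1875 loci with at least 100 reads and 220 of the 275 with at least 1000, so 16.7% is set largely by depth. AATAAA, the canonical polyadenylation signal, stood in the 40 nt before 41.4% of the 7309 sites with that much tag, which held 52.6% of their reads, and its first base lay at a median of 19 nt before the end. A single variant or several variants stood before others, of which AATGAA was the most frequent with 6.53% of sites, and 19.6% of sites had none.

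The signal was compared between the sites of a locus, in the 960 loci with several sites and enough tag. The most used site carried AATAAA in 42.5% of loci, with an interval of 39.4% to 45.7%, and the other sites in 23.6%, with an interval of 21.4% to 25.9% (Fisher's exact test, p = 1.43e-21). By position the contrast was wider: 15.5% of the sites farthest upstream carried it, with an interval of 13.4% to 17.9%, and 48.1% of those farthest downstream, with an interval of 45.0% to 51.3% (Fisher's exact test, p = 1.35e-54). Leaving out ends that lie before A-rich sequence gave 40.5% against 25.3% and 21.3% against 44.5%. Where sites lie may build in part of both contrasts. The most common distance from the most used site to a site upstream of it was 19 nt. The first base of AATAAA also lay at a median of 19 nt before the end. An upstream end that stops right before the AATAAA of a later site has that signal outside the window searched. How much of the contrasts this makes was not tested, so they do not show weaker signal use at upstream sites. Fisher's test also treats sites as independent, though the sites compared came from the same loci and the windows of close sites overlap. Its p-values ignore this pairing. Sites are not independent samples of worms.

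**Figure D2:**
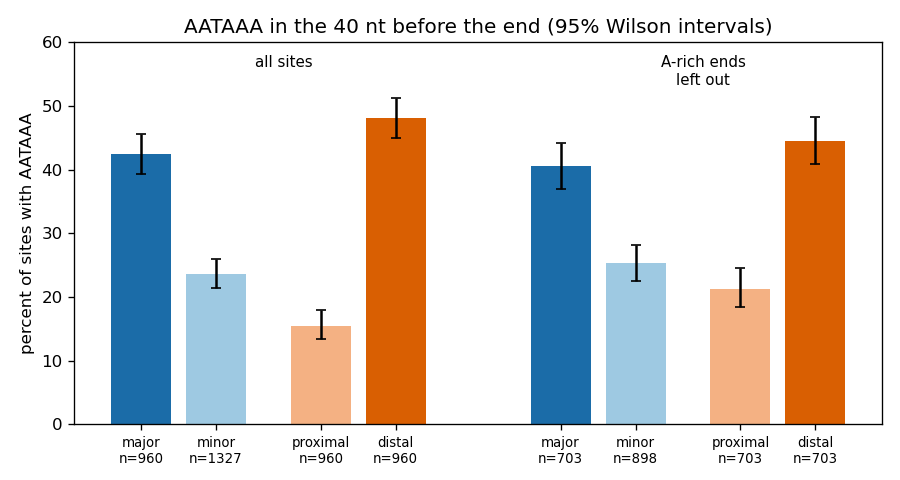
Percent of sites with AATAAA in the 40 nt before the end, with 95% Wilson intervals, for the most used (major) and other (minor) sites and for the sites farthest upstream (proximal) and downstream (distal), over all sites and without ends before A-rich sequence. Distal sites carry the signal at 48.1% and proximal sites at 15.5%. A proximal end right before the AATAAA of a later site has that signal outside the window searched.

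Many second sites lay close to the main one. Of 784 loci with a site upstream of the most used site, 301, or 38.4%, had it 15 to 22 nt upstream, and 19 nt was the most common spacing.

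**Figure D3:**
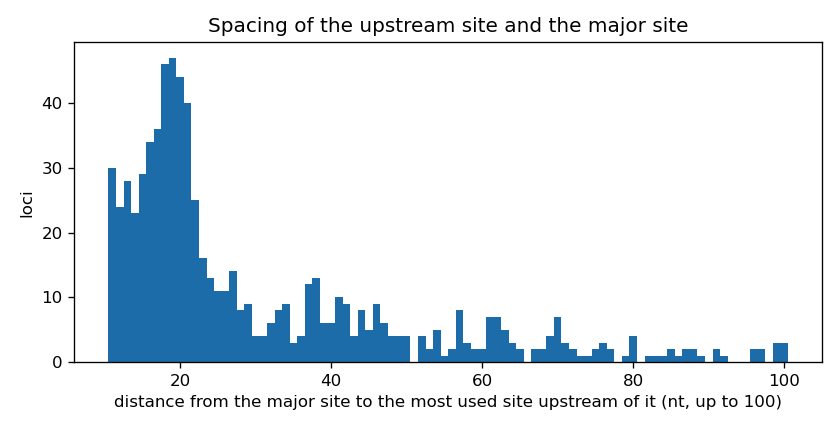
Number of loci by the distance in nt, up to 100, from the most used site to the most used site upstream of it. The most common distance is 19 nt.

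Whether messages grow longer or shorter with age was asked in 75 loci with several sites and enough reads in all 12 libraries of the shared stages. Ends before and after a GATC generally fall in different loci, so changes in length across a GATC could not be seen. No trend with stage was found: Pearson's r with stage order was 0.0160 (permutation p = 0.951) and Spearman's rho -0.0565 (permutation p = 0.845). Within the pilot r was -0.756 (exact permutation p = 0.0917, adjusted over the 3 correlations 0.275) and rho -0.771 (exact permutation p = 0.103). Within the full experiment r was 0.473 (exact permutation p = 0.406) and rho -0.0857 (exact permutation p = 0.919). Ends lay farther downstream in the pilot than in the full experiment at 5 of 6 stages, by a mean of 3.30 nt ± 3.61 (SD over stages, exact sign-flip p = 0.0938). Without the embryo and adult libraries r was -0.261, and r was also negative without any 1 of 6 libraries, the lowest being -0.195 without the full adult hermaphrodite library, so no direction is established.

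**Figure D4:**
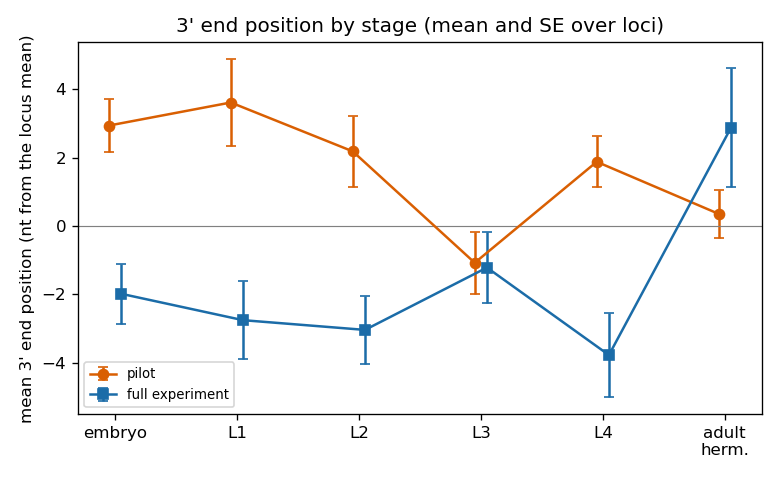
Mean 3′ end position by stage in nt from the mean of each locus, over 75 loci, with standard errors over loci, for the pilot (circles) and the full experiment (squares). Higher values lie farther downstream. Pilot values lie above those of the full experiment at 5 of 6 stages.

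The use of alternative sites within a locus, and so generally after the same GATC, differed by stage in 6 of 1286 loci in edgeR's test. In all 6 the second site lay 14 to 20 nt upstream of the main one. In 5 of them it stood before at least 6 A in the next 10 nt, with 5 A in the other. In all but tag-00003 it ended right before AATAAA, or AAATAAA, in the tag of the main site. At tag-00003 it ended inside ATTAAA. Priming on A-rich sequence inside the message, or tail removal that stopped there, is therefore not excluded. None met the rule for naming, so the examples here were chosen after their values were seen. At tag-00198 (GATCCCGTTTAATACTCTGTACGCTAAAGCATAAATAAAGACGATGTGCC) the main site took 100% of 376 embryo reads and 31.9% of 116 L3 reads (edgeR adjusted p = 0.0145). At tag-00007 (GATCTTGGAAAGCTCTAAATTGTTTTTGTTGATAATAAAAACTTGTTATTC) it took 99.7% of 9244 L2 reads and 69.3% of 5679 L1 reads (edgeR adjusted p = 9.36e-05). Site use differed between the 2 experiments in 20 loci. The 6 became 0 without the pilot embryo library, 1 without the full embryo library, 39 without the pilot adult hermaphrodite library, 20 without the full one, and 2 to 4 without any 1 of the other 8 libraries.

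RACE gave a second reading of the same ends from separate RNA. Its 8 sets held 13886 to 17944 reads. Of all RACE reads 25.8% ± 1.51 (SD, n = 8) could be placed on a capture locus, on 690 ± 30.3 loci per set (SD, n = 8). Ends of 22.7% ± 1.27 of all reads (SD, n = 8) lay within 10 nt of a capture site of at least 10 reads, against a background of 0.00183% ± 0.00396 with ends shifted by 200 nt and 4.20% ± 0.434 with a shift of 25 nt. Of the placed reads 88.0% ± 1.27 (SD, n = 8) ended within 10 nt of a site. The sets are parts of 1 clone collection, not separate worms.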

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

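The tests of sequencing depth, of adult stage, and of A-rich sequence and tail removal were chosen only after the results they explain were seen, and those of few molecules, of longer tags and of the adult libraries alone were written before.

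The adult hermaphrodite library of the full experiment held few loci. Depth alone is argued against: 40000 reads drawn from it held 1063 loci, against 2697 to 6082 in the other 16 libraries, and 20000 reads drawn outside the most read locus held 757, against 1609 to 3738. Adult stage is argued against too, since the same draw from the pilot adult library held 3231. Of loci at 100 CPM (reads scaled to equal library size) or more in the pilot adult library, 59.47% had no read in the full one, against at most 8.778% at the other 5 stages, as amplification from few molecules may give, but another cause of low complexity would give the same. The source stays open, and a difference between the worms or the RNA of the 2 experiments was not tested.

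Upstream ends carried AATAAA less often than downstream ends. Priming on A-rich sequence inside the message may make part of them: 50.47% of the upstream ends stood before at least 6 A in the next 10 nt of a longer tag, against 9.853% of other positions in the same tags. No tag ended in A, so tail removal can itself move an end to just before a run of A. The other positions had to follow a base other than A but were not required to stand before A. Part of the excess may thus be built in. Without the ends before at least 6 A the difference between proximal and distal sites was still -23.19 points (Fisher's exact p = 1.94e-20, with the pairing within loci ignored). That does not tell whether priming is the whole cause, since ends before fewer A, and ends without a longer tag to check, stayed in. At the ends before at least 6 A, a median of 60.67% of the reads ran on to a later site. These ends were chosen for having one, so the value does not tell whether tail removal stopped at A-rich stretches. That, and true upstream sites with weaker signals, stay open. The position of the ends may also build in part of the difference. An end right before the AATAAA of a later site has that signal outside the window searched. The share of the difference that this makes was not tested.

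Ends lay farther downstream in the pilot than in the full experiment in the same loci, by a mean of 3.30 nt (exact sign-flip p = 0.0938). The adult libraries are not the source alone, since their own ends went the other way, at 0.355 nt in the pilot and 2.88 nt in the full experiment. Leaving them out therefore had to raise the mean. It was then 4.507 nt in 118 loci, with the pilot farther downstream at 5 of 5 stages (exact sign-flip p = 0.0625). Longer tags may have been favoured in the pilot: across 1925 loci, which are not independent, tag length had a Spearman's rho of 0.5157 with the log2 ratio of pilot to full level (permutation p = 0.0001, the smallest that the permutations can give). The design gives no biological explanation, as the stages are the same, and a difference between the cultures was not tested.

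Other values stood out within their groups, with 4 such values among 37 groups tested, where chance alone gives about 1 in 20. The daf-2 library held 76290 reads, rounded, against 50330 to 53500 in the other dauer libraries. In the daf-9 library 17.44% of reads began with GATC and a remnant of 3 of its bases, against 7.303% to 8.44% in the others. Major sperm protein loci took 0.002127% of the reads of the daf-7 library, which is 1 read, and 0 in the other 3. In RACE set F 0.01115% of ends shifted by 200 nt lay near a capture site, against at most 0.003504% in the other 7 sets.

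Signals outside the comparisons also appeared. The authors' alignments placed 32 RACE reads on the mitochondrial genome. Of the polyA capture reads, 8.923%, or 217470 in all, were too short for a locus or fell in none.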

How the results depend on the processing

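Alternatives on locus rules, small sites, the doubtful library, the extreme stages and sequence agreement, and all those for families and chromosomes, were chosen after seeing the data, and the rest were planned. Both comparisons of the AATAAA signal kept their direction and passed their test, which ignores the pairing of sites within loci, in all 12 alternatives. The named loci were picked for large changes without overlap between groups, and most had no reads in the lower group. A change of direction was thus hardly possible for them, and its absence says little. Of the 19 changes of named loci, none changed direction in 108 values under other settings and 76 with a library left out, but 23 and 21 of these no longer passed the threshold.

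Counts of changed loci moved with several settings, and the cause was not tested except where fewer loci or libraries enter. With no filter on low counts, which adds loci to the adjustment, L1 against embryo gave 24, L4 against L3 5, adult hermaphrodite against L4 0, dauer against L3 92, male against hermaphrodite 3 and the 6 stages 413. With at least 10 reads in 2 libraries, adult against L4 gave 18 and male against hermaphrodite 46, and DESeq2 size factors gave 73 for the latter, all higher in males. DESeq2's own test gave 15 for L2 against L1, 1 for L3 against L2, 1 for L4 against L3, 89 for adult against L4 (12 higher and 77 lower in adults) and 522 for the 6 stages. A merge ratio of 20 gave 2 for L2 against L1. With the full adult hermaphrodite library kept out of the shared spread, whose coefficient of variation then fell from 0.854 to 0.681, the counts were 628 for L1 against embryo, 40 for L2 against L1, 2 for L3 against L2, 53 for L4 against L3 and 590 for dauer against L3.

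With no replicate block, that is without the term for the experiment, L1 against embryo gave 182, L2 against L1 0, L4 against L3 6, adult against L4 2 and site use 0. The block moved no other count by more than 1.5 times.

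With 1 library left out in turn, the counts ranged from 18 to 182 for L1 against embryo, 0 to 1 for L2 against L1, 0 to 0 for L3 against L2, 1 to 18 for L4 against L3, 0 to 589 for adult against L4, 18 to 712 for male against hermaphrodite, 43 to 256 for dauer against L3, 279 to 1550 for the 6 stages and 0 to 39 for site use. A group left with 1 library was assumed to vary like the others. The share of RACE ends near a site ranged from 22.5% to 23.0% with a set left out.

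Site use gave 3 loci with ends joined within 5 nt, 0 within 20 nt, 1 with sites of at least 5% of the locus, and 58 with limma, which included the 6. The RACE share was 21.1% within 5 nt and 18.6% with sites of at least 20 reads.

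The correlation of end position with stage, which passed no test, changed sign. It was -0.0415 with at least 5 reads, -0.0449 with at least 20, -0.115 with the median over loci, -0.756 in the pilot only, -0.261 without the embryo and adult libraries, and -0.195 to 0.221 with 1 library left out.

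Tests of the fixed gene lists were not run, because tags could not be paired with genes, so their alternative with an estimated correlation was not run either. Depth and the spread between libraries limit the comparisons: in the simulated L4 against L3, 28% of loci changed 32-fold were called.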

Other observations

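The tests here, on loci by chromosome and on actin, were chosen after the tags had been seen. RACE alignments placed 943 loci on chromosomes, 91 of them on chromosome X. Of the 43 X loci tested, 11 rose and 1 fell from embryo to L1, with a median log2 change of 2.86 and a camera adjusted p = 0.0102 over the 6 chromosomes, but adjusted p = 0.478 with an estimated correlation. From L3 to dauer 1 was higher and 7 were lower, with a median of -1.24 and a camera adjusted p = 0.0217, but adjusted p = 0.606 with an estimated correlation. Lower loci were not particular to X. On chromosomes IV and V, 14 of 87 and 14 of 99 tested loci were lower in dauers. On I, II and III these were 7 of 98, 10 of 89 and 7 of 72. The share of reads in placed loci on X did not follow. From embryo to L1 it fell in the pilot, from 3.10% to 2.89%, and rose in the full experiment, from 3.67% to 5.38%. In dauers it ran from 4.48% to 6.77%, around the 5.44% of the full L3 library and above the 2.46% of the pilot one. No chromosome passed the test between males and hermaphrodites, where camera gave an adjusted p = 0.757 for X and 3 X loci were higher in males. The share of the reads in placed loci that fell on X was nonetheless 9.18% in the 1 male library (95% exact binomial interval 8.87% to 9.48%), the highest of the 17 libraries, against 4.51% and 3.23% in the hermaphrodite libraries.

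The actin locus, tag-00242, rose from embryo to L1 by 3.50 ± 1.22 on the log2 scale (SE, edgeR adjusted p = 0.0408). In dauers it had 2 reads, against 116 in the full L3 library and 87 in the pilot one (edgeR adjusted p = 7.10e-05). Within the full experiment it was lower in dauers by a ratio of 83.5, with a counting interval of 27.7 to 856.

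The DpnII overhang GATC is also the barcode of the L2 and daf-9 libraries. In the full L2 library 37.0% of reads began with GATCGATC, against at most 0.510% in the other 16 libraries.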
